A study of Mus musculus with 16 samples.

How the data were processed

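Anti-CMS sequencing measures 5-hydroxymethylcytosine (5hmC) by treating sheared, adapter-ligated genomic DNA with bisulfite, which turns 5hmC into cytosine 5-methylenesulfonate (CMS), and by pulling down the fragments that carry CMS with an antiserum. Per the labels, the 16 libraries came from V6.5 mouse embryonic stem cells, from clones of the same line that stably express a short hairpin RNA against Tet1, and from clones with a hairpin against Tet2. Each condition had 3 immunoprecipitated (IP) libraries. Input DNA, which was not pulled down, had 3 libraries for parental cells, 3 for Tet2 knockdown cells and 1 for Tet1 knockdown cells. The labels number biological replicates, and parental and Tet2 knockdown libraries 1 and 2 share a number, so these groups hold 2 biological replicates each and the Tet1 knockdown IP holds 3.

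The values used here are the authors' tables of 300-bp genome windows, 1 for each knockdown against parental cells. The authors counted whole reads per window, and the deposited counts stand in a single column per condition for IP and for input, per the file headers; which libraries were pooled into each column is not given in the sources used here. The deposited RPKM values are reads per kilobase of window scaled to the total reads of the condition, per the file headers. The column names carry the names of MEDIPS, a package for enrichment sequencing, and edgeR, and the submitters' processing notes name edgeR and the mouse genome build mm9. Versions, the aligner and the handling of duplicate reads are not given in the sources used here. The deposited log2 fold changes are parental over knockdown, and their sign was turned here so that a negative value means less signal in the knockdown. They differ from the log2 ratio of the deposited RPKM by a constant of -0.14 for Tet1 and -0.17 for Tet2, a composition factor by the authors that moves every window towards loss. The deposited p-values come with an adjusted p that equals p times 8849662, the number of windows, with a ceiling of 1, which is the Bonferroni adjustment. Every deposited p-value lies below 1e-04, so the tables hold windows that passed this selection and not all windows that were counted.

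Because the windows had been selected for their p, no new test was used to call them: a test on windows picked for a small p-value is void. Where alternatives recompute p on the listed windows, they show only which of the listed calls remain. The description follows the authors' deposited calls, and a window is called lost or gained by the sign of the deposited fold change. The deposited p-values were recomputed with edgeR's exact test and an assumed variation between libraries of 1%: the median ratio of the recomputed to the deposited log10 p was 0.998 for Tet1 and 0.997 for Tet2, and 96.7% and 98.4% of windows lay within 5%. At an assumed variation of 20% the ratio dropped to 0.567 and 0.487. The deposited p-values therefore carry the counting error of pooled reads and no measured spread between libraries.

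The total reads behind each column were recovered from its counts and RPKM values. They were 48024429 for the parental IP, 18886597 for the Tet1 knockdown IP and 32130680 for the Tet2 knockdown IP, and 48119177, 20071252 and 37480871 for the inputs in the same order. The mean was 5.43, 2.13 and 3.63 IP reads per window. A window without reads in the knockdown was listed from 25 parental reads in the Tet1 comparison and from 17 in the Tet2 comparison. Folds against 0 reads use a floor of 3 reads over the pooled column, and they leave out the counting error of the other column. The parental counts of the 3081 windows present in both tables were identical, so both comparisons share the same control reads. Counts have exact Poisson intervals and ratios of counts have exact binomial (Clopper-Pearson) intervals at 95%. All intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules and no spread between libraries can be had. They also leave out that listed windows were picked for their difference, which widens the apparent fold.

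Choices made before the data were examined were the groups, the listing threshold, the merging rule, the overlap of identical windows and the rule for naming regions. Called windows of the same direction that touched or lay within 1 window of each other were merged, and for each knockdown and direction the 6 regions with the most called windows are named, with ties broken by the larger mean change. Where these lay in places with shifted input, further regions elsewhere were added after their values were seen, by the same order. Region levels sum the reads of the listed windows of the region. Intervals of medians, shares and densities over windows come from resampling 1-Mb blocks. Input reads at the listed windows were compared along each chromosome with a scan for the best single segment in 1-Mb steps, leaving out windows with 60 or more parental input reads. The scan, tested on simulated data for chromosome 2, found 99 of 100 segments of 40 bins with an input ratio of 0.5 to within 2 bins in each comparison, and its highest score without a segment was 10.7 for Tet1 and 11.2 for Tet2. The best segments scored 355 for Tet1 and 77.9 for Tet2, and these with chromosome 8 and the run at the start of chromosome 1 are the places with shifted input. Another 6 Tet1 segments outside chromosome 8, up to a score of 21.4, and 0 Tet2 segments also exceeded the simulated score and were not counted among these places. The recomputed edgeR test, run on simulated data for the 23890 windows of the Tet1 comparison, recovered 58% of 4-fold and 21% of 2-fold changes and called 2 of 23690 unchanged windows. For the 67771 windows of the Tet2 comparison it recovered 90% of 4-fold and 25% of 2-fold changes and called 3 of 67571 unchanged windows. With 20% variation between libraries added, 241 (1.02%) and 1259 (1.86%) unchanged windows were called. The overlap that a shared parental column gives with no effect was simulated over 8849662 unchanged windows.

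Alternatives covered the adjusted p, the composition factor, differing input, sex chromosomes, merged regions, an assumed variation of 10% and 20%, the input ratio as an offset, other scalings and thinned reads. A fit of single libraries, a replicate block, DESeq2 size factors and leaving out a library need separate columns and were not run. The CpG content and the gene or promoter location of the windows, the named genes and the gene lists fixed in advance (regulators of pluripotency, DNA modification enzymes, lineage and signalling genes, Hox, imprinted, germline and housekeeping genes) need an annotation of mm9, which was not used here, so positions are given without gene names. RNA and methylcytosine data of the same cells, and the level of Tet1 and Tet2 RNA, are not analysed here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.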

Results

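Tet1 and Tet2 are dioxygenases that oxidise 5-methylcytosine to 5-hydroxymethylcytosine (5hmC), and both are expressed in mouse embryonic stem cells. The series asks how their roles differ. Anti-CMS sequencing located 5hmC in parental V6.5 cells, an embryonic stem cell line, and in derived clones depleted of Tet1 or of Tet2 by a stably expressed short hairpin RNA. There were 3 IP libraries for each of the 3 conditions and 7 input libraries, pooled by the authors into a single count per condition and 300-bp window. The pooled depth was 48024429 reads for the parental IP, 18886597 for the Tet1 knockdown and 32130680 for the Tet2 knockdown. The pooled columns give no spread between replicates, so no difference could be set against one. No library came from a control hairpin or a control clone. An effect of depletion therefore cannot be told apart from effects of deriving the clones, and depletion below names the condition and not a cause.

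Depletion of Tet1 was followed by both gain and loss of 5hmC signal, with more windows gained. In the authors' deposited table, 14925 of 23890 listed windows (62.5%) were higher in Tet1 knockdown cells than in parental cells, and 8965 (37.5%, block interval 35.6% to 39.4%) were lower. The gained windows had a median IP level of 0.902 RPKM in parental cells, against 0.762 RPKM in parental input, and reached 5.29 RPKM in the knockdown, where input was 0.830 RPKM. The lost windows fell from a median of 5.76 to 1.59 RPKM with a knockdown input median of 0.996 RPKM. In the authors' deposited table the median log2 fold change was 2.43 (quartiles 1.89 and 3.10) for gained windows and -1.94 (quartiles -2.70 and -1.51) for lost windows. An adjusted p under 0.05 in the authors' deposited table was reached by 3165 gained and 370 lost windows. Outside the places with shifted input described further on, 2975 gained and only 117 lost windows reached it. In 157 gained windows parental cells had no IP read. With the floor of 3 reads in place of 0, the smallest fold among them was 10.2. In 837 lost windows the knockdown had no IP read, and the smallest fold by the same floor was 3.28. Neither value covers the counting error of the other column.

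The balance of gain and loss in Tet1 knockdown cells depended on scaling. Without the authors' composition factor, 23.2% of the listed windows that still passed a p of 1e-04 were lost, and scaled to the IP over input ratio of a run of windows at the start of chromosome 1 the share was 3.90%. With 20% variation between libraries assumed the counts were 481 lost and 4649 gained windows. The simulation of unchanged windows also leaned towards gain for Tet1. It called at most 13 lost and at most 60 gained without added variation. With 20% variation between columns it called 398 lost and 1048 gained, and for Tet2 1378 lost and 1748 gained. A lean towards gain can therefore arise without any change, and its part in the observed Tet1 balance was not estimated. Outside the places with shifted input described further on, 6609 windows were lost and 14166 gained, and over those with fewer than 60 parental input reads the input changed by -0.30 on the log2 scale at lost windows (block interval -0.32 to -0.28) and by 0.05 at gained windows.

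**Figure D1:**
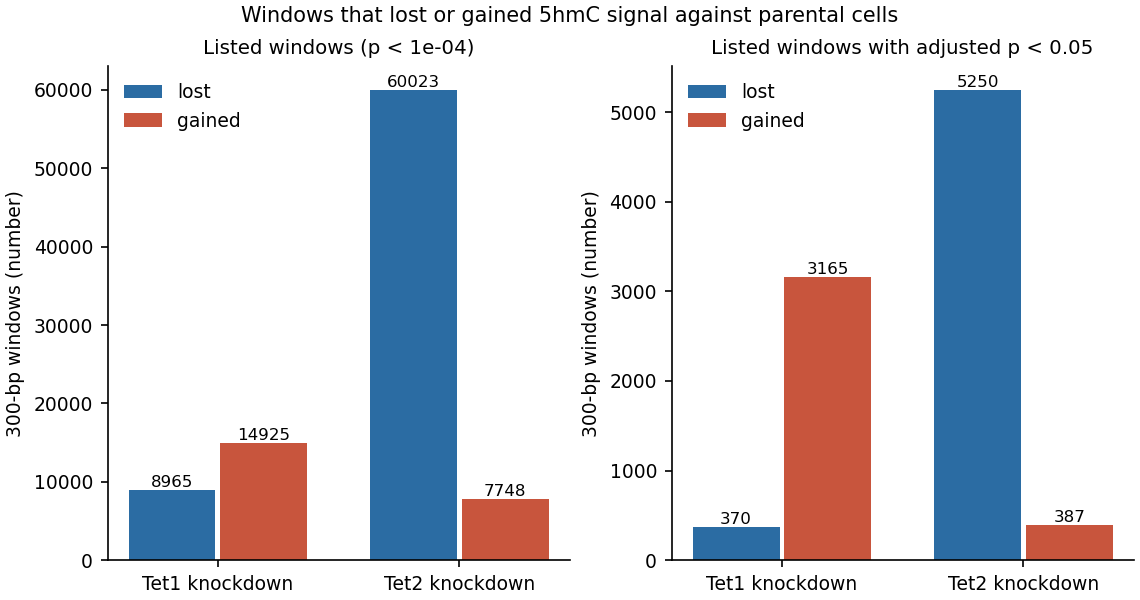
Number of 300-bp windows (vertical axes, linear, different ranges) that were lost (blue) or gained (red) in each knockdown against parental cells, for all windows listed by the authors (left) and those with an adjusted p under 0.05 (right). The Tet1 knockdown had 8965 lost and 14925 gained windows and the Tet2 knockdown 60023 lost and 7748 gained. Both panels include windows in the places with shifted input.

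Windows gained after Tet1 depletion formed short regions, and 5 of the 6 named here had little IP signal in parental cells. Merging gave 11044 gained regions, of which 7416 were single windows, and 7108 lost regions, of which 5712 were single windows. The region with the most gained windows was chromosome 3, 43745701 to 43748100 (mm9), with 7 windows: its IP level rose from 0.297 RPKM (95% interval 0.201 to 0.425) to 3.40 RPKM (2.85 to 4.03), an 11.4-fold increase (7.66 to 17.6). A pair of neighbouring regions on chromosome 10, 112255801 to 112257900 and 112259101 to 112261200, rose 14.9-fold (10.2 to 22.6) and 16.9-fold (11.3 to 26.1). Chromosome 1, 166465201 to 166466700, rose 21.6-fold (14.4 to 33.4), from 0.375 to 8.08 RPKM. Chromosome 8, 4531501 to 4533000, rose 26.1-fold (16.8 to 42.5), from 0.305 to 7.98 RPKM, while input was nearly absent in both conditions, with 3 parental reads where the mean input depth gives 27.2 and 0 knockdown reads where it gives 11.3. Chromosome 4, 118219801 to 118221600, began higher, at 6.44 RPKM, and rose 4.77-fold (4.30 to 5.30) to 30.7 RPKM, with input levels of 9.32 and 7.61 RPKM. Its parental input held 807 reads where the mean input depth gives 32.6. None of these 6 gained regions had a listed window in the Tet2 table.

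The 6 regions with the most windows lost after Tet1 depletion all lay in places where the input also differed. A run of 162 windows at the start of chromosome 1, 1 to 48600, fell from 44.8 to 19.9 RPKM, and its input fell from 76.5 to 44.5 RPKM. On chromosome 6, region 83664301 to 83667300 was 4.52-fold lower (3.65 to 5.66), region 52154401 to 52156800 was 5.43-fold lower (3.98 to 7.59) and region 83139301 to 83141400 was 3.84-fold lower (3.13 to 4.76). Their inputs changed by -0.94, -1.17 and -2.07 on the log2 scale. For region 83139301 to 83141400 the input change rests on 13 knockdown reads (interval -3.02 to -1.25). Subtracting this change gave 0.13 in place of -1.94, a value that the interval does not tell from 0. On chromosome 8, region 72404701 to 72407400 was 3.29-fold lower (2.74 to 3.97) and region 114151801 to 114154200 was 2.95-fold lower (2.43 to 3.60), with input changes of -0.74 and -0.56. The next 4 lost regions outside these chromosome-scale places were chosen after their values were seen. Among them, chromosome 14, 68741401 to 68743200, fell from 10.5 RPKM (9.83 to 11.2) to 1.21 RPKM (0.865 to 1.64), 8.71-fold lower (6.37 to 12.2), with a log2 input change of -0.06, and 5 of its 6 windows were also listed as lost in Tet2 knockdown cells. Chromosome 12, 74139901 to 74142300, was 4.37-fold lower (3.17 to 6.18) with an input change of -0.39, and its only window in the Tet2 table was gained. Chromosome 15, 75833701 to 75835800, was 2.39-fold lower (1.96 to 2.94) with an input change of 0.02. Chromosome 2, 25432501 to 25434300, was 3.63-fold lower (2.90 to 4.58), but its input also changed by -0.90 (-1.46 to -0.37), which leaves a log2 change of -0.96 once subtracted.

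Depletion of Tet2 was followed mainly by loss of 5hmC signal. In the authors' deposited table, 60023 of 67771 listed windows (88.6%, block interval 87.8% to 89.2%) were lower in Tet2 knockdown cells and 7748 (11.4%) were higher. The lost windows fell from a median of 4.51 RPKM in parental cells to 1.45 RPKM, near the input medians of 1.11 and 1.16 RPKM. The gained windows rose from 0.625 to 3.42 RPKM, with input medians of 1.18 and 1.16 RPKM. In the authors' deposited table the median log2 fold change was -1.81 (quartiles -2.25 and -1.48) for lost windows and 2.20 (quartiles 1.73 and 2.95) for gained windows, and an adjusted p under 0.05 was reached by 5250 lost and 387 gained windows. Outside the places with shifted input 53208 windows were lost and 7208 gained, of which 4351 and 214 reached that adjusted p. Input at the 53208 lost windows changed by 0.02 on the log2 scale. Without the authors' composition factor 33715 of the listed lost windows passed a p of 1e-04 and 81.3% were lost, and scaled to the IP over input ratio of the chromosome 1 run 1963 gained windows passed and 96.8% were lost. With Tet2 knockdown reads thinned to the depth of the Tet1 knockdown, 23951 lost and 3553 gained windows passed a p of 1e-04, and with 20% variation between libraries assumed the counts were 3805 and 539.

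**Figure D2:**
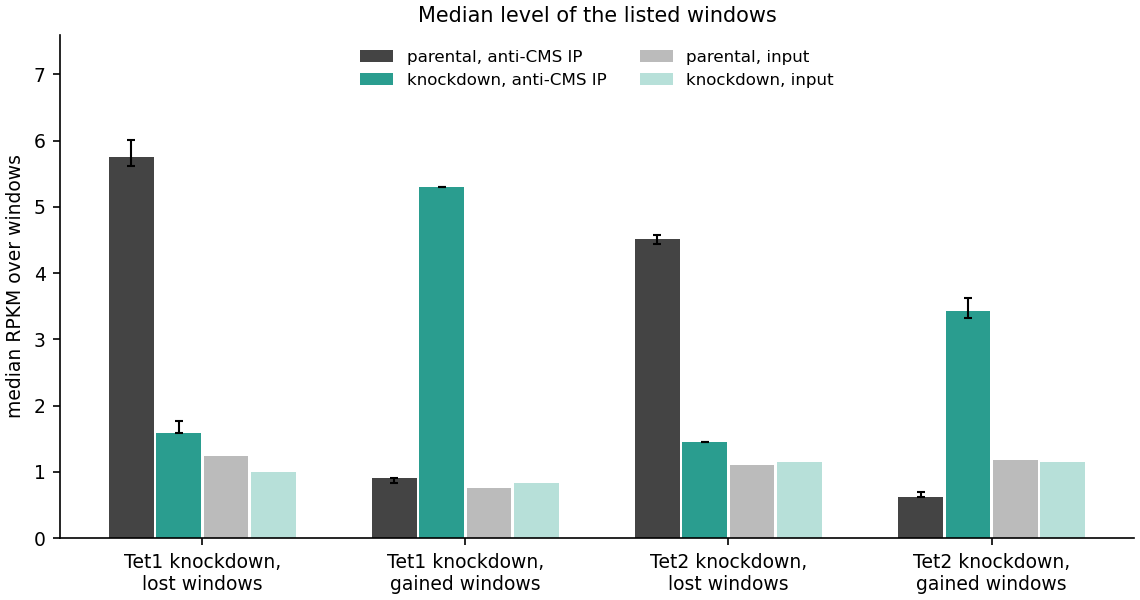
Median RPKM (vertical axis, from 0) of the lost and gained windows of each knockdown, in the IP and in the input of parental and knockdown cells. Error bars on the IP bars are 95% intervals from resampling 1-Mb blocks, and the input bars carry none. Lost windows of the Tet2 knockdown fell from 4.51 to 1.45 RPKM and gained windows of the Tet1 knockdown rose from 0.902 to 5.29 RPKM.

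Windows lost after Tet2 depletion lay singly and in stretches of several windows. Of 41590 lost regions, 27966 were single windows and 387 had at least 5 windows, lengths that grow with the number of listed windows and were not compared between the knockdowns. The region with the most windows was chromosome 4, 141027301 to 141035700, where 25 listed windows fell from 10.7 RPKM (10.4 to 11.1) to 5.13 RPKM (4.85 to 5.43), 2.09-fold lower (1.96 to 2.23), and 4 of its windows were lost and 1 was gained after Tet1 depletion. Near the end of the X chromosome, 166421101 to 166428600, 21 windows fell 2.09-fold (1.99 to 2.20) from 22.6 to 10.8 RPKM. Input there was 4.80 RPKM in parental and 4.84 RPKM in knockdown cells, unchanged within its interval (log2 change 0.01, -0.10 to 0.13). The parental input held 1456 reads where the mean input depth gives 114. Both windows of this region in the Tet1 table were gained. Chromosome 15, 96519301 to 96524700, was 3.44-fold lower (3.01 to 3.93) over 16 windows, and none of these was listed in the Tet1 table. On chromosome 8, regions 28260601 to 28265400, 90304201 to 90308700 and 91553401 to 91557300 were 2.21-fold (2.01 to 2.43), 3.23-fold (2.91 to 3.60) and 3.32-fold (2.96 to 3.72) lower. Chromosome 2, 180965701 to 180969900, chosen after its values were seen, was 2.49-fold lower (2.21 to 2.81).

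Gains after Tet2 depletion were mostly isolated, with 5195 of 6305 gained regions made of a single window. The run at the start of chromosome 1 rose from 44.8 to 82.1 RPKM, and its input rose from 76.5 to 98.5 RPKM. Chromosome 17, 39979801 to 39983400, rose 1.59-fold (1.55 to 1.64) from 47.2 to 75.3 RPKM over 12 windows, at an input level of 52.9 RPKM in parental and 53.1 RPKM in knockdown cells, and 6 of its windows were listed as lost in Tet1 knockdown cells. Its parental input held 9156 reads where the mean input depth gives 65.2. Scaled to the chromosome 1 run, its log2 change was 0.16 in place of 0.67. Chromosome 3, 89152801 to 89154300, rose 5.30-fold (3.93 to 7.24) from 0.791 to 4.19 RPKM. Chromosome 1, 74170801 to 74172300, rose 4.47-fold (3.48 to 5.79). Chromosome 13 held the other 2, at 55572901 to 55574700 and 55613701 to 55615200, which rose 4.65-fold (3.61 to 6.02) and 4.17-fold (3.26 to 5.36) in a segment with raised input. Chromosome 9, 3000001 to 3001500, chosen after its values were seen, rose 1.54-fold (1.47 to 1.63) with a log2 input change of 0.36 (0.29 to 0.43). Its parental input held 2956 reads where the mean input depth gives 27.2. Scaled to the chromosome 1 run, its log2 change was 0.12 in place of 0.63.

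**Figure D3:**
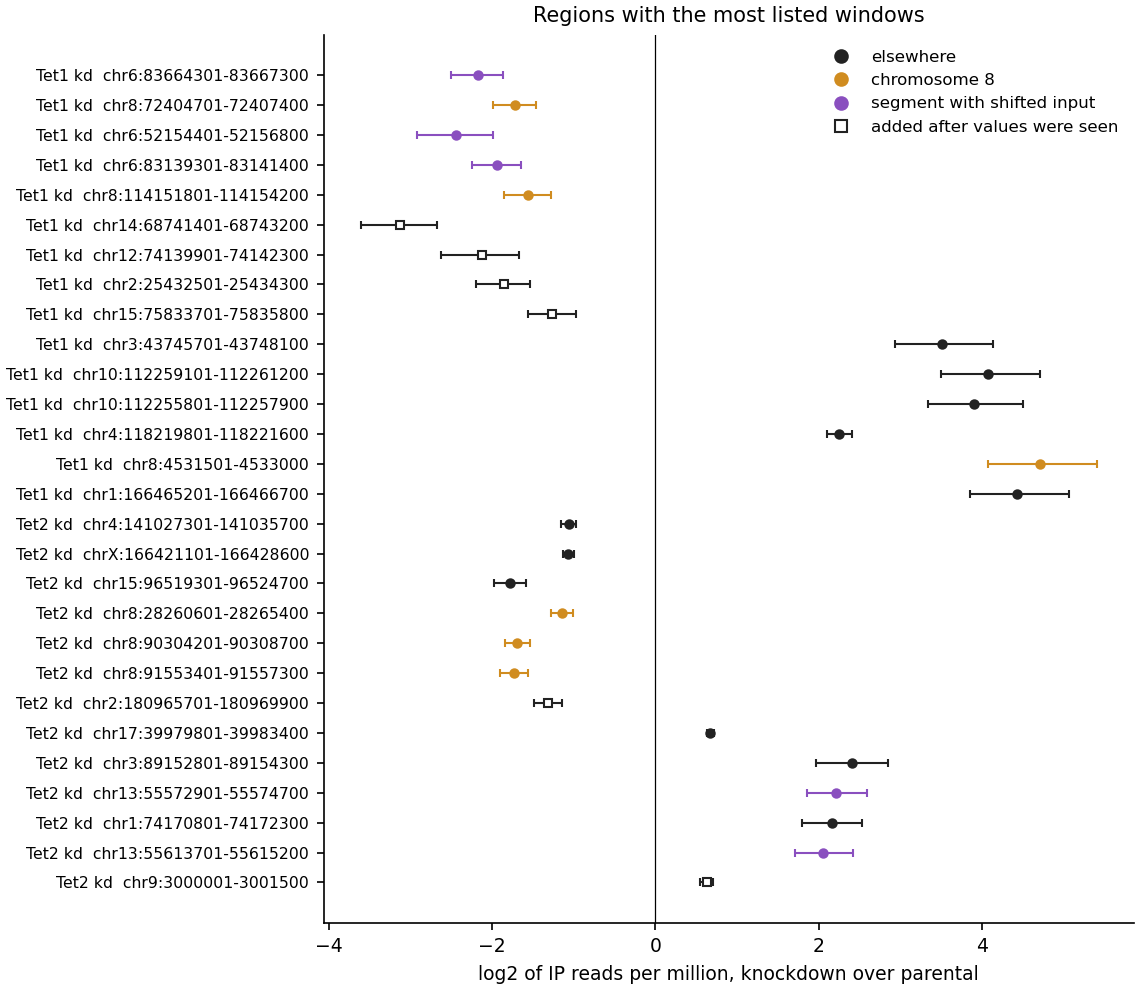
Log2 ratio of IP reads as a share of all reads, knockdown over parental (horizontal axis), for the regions with the most listed windows other than the chromosome 1 run. Points are ratios of summed reads with 95% counting intervals, open squares were added after their values were seen, and colours mark chromosome 8 and the segments with shifted input. The values run from -3.12 on chromosome 14 to 4.71 on chromosome 8 in the Tet1 knockdown.

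Lost windows were spread unevenly over the chromosomes. After Tet1 depletion chromosome 8 held 9.64 lost windows per Mb (block interval 7.12 to 12.2) and chromosome 6 held 7.37 (5.09 to 9.85), against 3.23 on the median autosome. After Tet2 depletion chromosome 8 again stood highest, with 51.5 lost windows per Mb (41.3 to 61.2) against a median of 22.2. Gained windows were densest on chromosome 11 in both knockdowns, at 8.01 per Mb (7.01 to 9.03) for Tet1 and 5.22 (4.20 to 6.27) for Tet2. The X chromosome had 39 lost and 316 gained windows after Tet1 depletion and 254 lost and 87 gained after Tet2 depletion.

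The input, which does not measure 5hmC, moved with several of these places. On chromosome 6 between 43 and 97 Mb, Tet1 knockdown input was 0.501 times parental input relative to the other chromosomes (block interval of the log2 ratio -1.05 to -0.95). Against windows of the same direction elsewhere, the ratio was 0.562 (0.540 to 0.581) at lost and 0.528 (0.411 to 0.643) at gained windows of the segment. In that segment 93.6% of 988 listed windows were lost, against 22.3% on the rest of the chromosome. On chromosome 8, input differed from the other autosomes by -0.26 on the log2 scale in Tet1 knockdown cells (-0.31 to -0.22) and by -0.21 in Tet2 knockdown cells (-0.22 to -0.19), and 64.6% and 96.5% of its listed windows were lost. On chromosome 13 between 54 and 56 Mb, Tet2 knockdown input was 1.41 times parental input, and 77.6% of 174 listed windows were gained, against 88.8% lost on the rest of the chromosome.

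**Figure D4:**
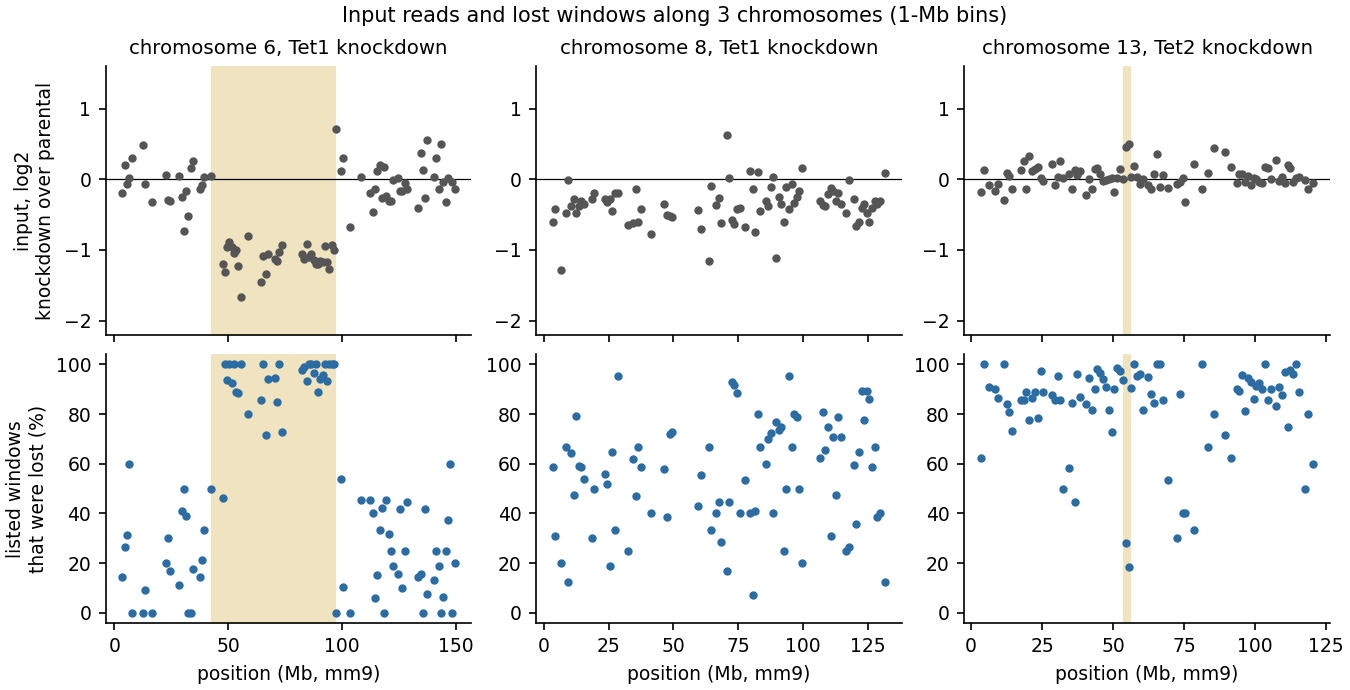
Log2 ratio of input reads at listed windows, knockdown over parental (top), and percent of listed windows that were lost (bottom), along chromosomes 6 and 8 for the Tet1 knockdown and chromosome 13 for the Tet2 knockdown. Each point is a 1-Mb bin with at least 5 listed windows, and shading marks the segments at 43 to 97 Mb and 54 to 56 Mb. Nearly all listed windows of the chromosome 6 segment, 93.6%, were lost.

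Loss in both knockdowns was the most frequent outcome among windows listed in both tables. Of 3081 such windows, 2629 were lost in both, 32 were gained in both, 237 were gained after Tet1 and lost after Tet2 depletion, and 183 went the other way, of which 162 were the run on chromosome 1. The windows lost in both made up 29.3% of the windows lost after Tet1 depletion and 4.38% of those lost after Tet2 depletion. Their median IP level was 7.91 RPKM in parental cells, 2.82 RPKM in Tet1 and 3.32 RPKM in Tet2 knockdown cells. Independent lists drawn from 8849662 windows, an upper limit for those that could be called, would share 60.8 lost windows, 13.1 gained windows and 101 windows gained after Tet1 and lost after Tet2 depletion. In a simulation of unchanged windows against the shared parental reads, at most 1 window was called in both, and with 20% variation between columns 94 were, of which 43 were lost in both and none had opposite signs. Part of the excess over either value may come from the shared parental reads, which cannot be split here.

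The same sign was found in 86.4% of windows listed in both tables (16.1% at an adjusted p of 0.01), and in 91.2% without the run on chromosome 1 (93.3% at that threshold). In the simulation of unchanged windows with 20% variation, all 94 windows called in both had the same sign. A high share therefore arises from the shared parental reads without any effect. Across the windows listed in both tables, which are not independent replicates, the Spearman correlation of the deposited log2 fold changes was 0.262. Their covariance without the run was 0.177, of which redrawn parental counts gave 0.0262, or 0.112 with 20% variation. The next totals leave out the shifted places of both knockdowns, while the earlier counts outside shifted input leave out only those of their own comparison. Suppose each window lost after Tet2 depletion had changed by the same fold after Tet1 depletion. Counting at the Tet1 depth would then have listed 21995 of 52721 windows (41.7%), whereas 1925 (3.65%) were listed as lost and 211 as gained. In the other direction 6443 of 6589 windows (97.8%) would have been listed after Tet2 depletion, whereas 1925 (29.2%) were listed as lost and 17 as gained. Folds of windows picked for a small p are too large, so these expected values are upper limits. With log2 changes 0.5 times as large, 1804 (3.42%) and 1703.4 (25.9%) would have been listed, near the observed values, so the listed windows leave open whether the same lost sites changed to a lesser degree. Of 14146 windows gained after Tet1 depletion, the same fold would have listed 13302.9 (94.0%) after Tet2 depletion and log2 changes 0.5 times as large 609.25 (4.31%), whereas 32 (0.226%) were listed as gained and 211 as lost. In the other direction the same fold would have listed 2932.85 of 6989 windows (42.0%) and log2 changes 0.5 times as large 13.55 (0.194%), whereas 32 (0.458%) were listed as gained and 17 as lost.

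The 237 windows gained after Tet1 and lost after Tet2 depletion had a median of 4.23 RPKM in parental cells, 12.2 RPKM in Tet1 and 1.35 RPKM in Tet2 knockdown cells, with input medians of 0.970, 0.830 and 0.978 RPKM. They formed 214 regions on 20 chromosomes, none longer than 2 windows. The 21 windows that went the other way outside the chromosome 1 run had medians of 5.76, 1.59 and 12.2 RPKM. Being listed as gained in one table and lost in the other requires both an intermediate parental level and a wide difference between the knockdowns, so neither is a finding. Examples chosen after their values were seen were chromosome 15, 25755301 to 25755900, at 3.85, 14.3 and 1.04 RPKM, which was 3.71-fold higher (2.90 to 4.77) after Tet1 and 3.71-fold lower (2.29 to 6.31) after Tet2 depletion. Chromosome 5, 106792501 to 106793100, stood at 3.82, 14.9 and 1.14 RPKM, and chromosome 11, 116541601 to 116542200, at 5.66, 26.8 and 2.59 RPKM.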

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

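All tests of explanations in this part were chosen after the results were seen. The input columns, which the comparisons of 5hmC do not use, showed shifts between conditions, and some windows moved in opposite directions in the 2 knockdowns.

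The first pattern is the cluster of windows lost after Tet1 depletion on chromosome 6 between 43 and 97 Mb, where Tet1 knockdown input was 0.501 times parental input. A fault of the single Tet1 knockdown input library is argued against by the IP reads, since gained windows per Mb in the segment were 0.182 times those on the rest of the chromosome. Since windows lost after Tet1 depletion had lower input elsewhere too, input was also compared between lost windows, and the ratio in the segment was 0.562 (0.540 to 0.581). Counting each window against the input ratio at windows of the same direction left 41 of 926 lost windows. Their density was 0.414 times that on the rest of the chromosome (0.172 to 0.818). The offset removed the excess, but it lowers the knockdown reads expected in the segment, so a loss is harder to call there. The density therefore cannot tell whether 5hmC was also lost beyond the DNA content. A lower copy number of the segment in the Tet1 knockdown cells remains open as a hypothesis and may account for these windows, and an effect of Tet1 on such a loss was not tested.

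The second pattern is the density of lost windows on chromosome 8 in both knockdowns, where input against the other autosomes changed by -0.26 (Tet1) and -0.21 (Tet2) on the log2 scale. Over windows lost in both knockdowns, parental input per window on chromosome 8 was 1.13 times that on other autosomes (1.08 to 1.18), and the higher of the knockdown ratios was 1.00 (0.962 to 1.04). More chromosome 8 DNA in the parental cells is therefore a candidate explanation, but a deficit in both knockdown lines cannot be told apart from it, because the listed windows give no baseline of chromosome 8 against other autosomes in normal cells. With the input ratio at windows of the same direction taken out, lost windows per Mb were 1.33 times the median autosome after Tet1 (0.745 to 2.22) and 1.28 times after Tet2 depletion (0.956 to 1.63). The intervals are too wide to exclude an additional loss of 5hmC on chromosome 8 in either knockdown.

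The third pattern is the run of 162 adjoining windows at the start of chromosome 1, which was lost after Tet1 and gained after Tet2 depletion, while the next listed window of the chromosome starts at 3325501. Input per window in the run was 203 times the genome mean in parental cells, and at least 118 times in each of the 3 inputs. A change of 5hmC with unchanged DNA is argued against, since the input of the run moved by -0.78 after Tet1 and by 0.36 after Tet2 depletion on the log2 scale. Reads of phage lambda control DNA placed there may be the source, a hypothesis from the length of the run and from its last window, which held 420 parental input reads against at least 615 in each other window. What was added to the libraries is not given in the sources used here.

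Other results are given as values. Tet2 knockdown input on chromosome 13 between 54 and 56 Mb was 1.41 times parental input. Input on chromosome 14 differed from the other autosomes by -0.0879 on the log2 scale in Tet2 knockdown cells (-0.11 to -0.07). Input at windows lost after Tet1 depletion outside the shifted places, with fewer than 60 parental input reads, changed by -0.30 on the log2 scale, and 32.7% of all lost windows outside these places had knockdown input at or above parental input, with a median log2 fold change of -1.98. That share was 50.9% at Tet1 gained, 50.5% at Tet2 lost and 46.7% at Tet2 gained windows. The input offsets covered only the shifted segments and chromosome 8, so the lower input at Tet1 lost windows elsewhere was not taken out. The 237 windows gained after Tet1 and lost after Tet2 depletion, and the 183 windows that went the other way, differ between the knockdowns in pooled reads, and the difference was not tested.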

How the results depend on the processing

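Alternatives chosen after seeing the data were the adjusted p of 0.05, the assumed variation, both input offsets, the scaling to the chromosome 1 run, the thinned reads, all sets without the run or the shifted places, and all alternatives for single regions. No paired analysis was possible because the deposited columns pool the libraries and carry no replicates. For the same reason the fits of single libraries, DESeq2 size factors and its Wald test, the low-count filter and leaving out each library were not run; other pseudocounts were not run because counts were used, and the alternatives for CpG content and genomic location were not run. In each alternative run for the counts, gained windows outnumbered lost windows after Tet1 depletion and lost outnumbered gained windows after Tet2 depletion. For Tet1, each rescaling and input offset moved windows towards gain and acted on listed windows only. Such alternatives could not turn the balance, so they do not test it. For Tet2, the scaling to the chromosome 1 run likewise moved windows towards loss. Over all results and named regions, 103 alternative values moved, 100 stayed and 1 changed sign. The causes of the shifts were not tested beyond how each alternative is built.

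For Tet1, the lost windows numbered 370 at an adjusted p of 0.05, 288 at 0.01 and 276 with a log2 fold change of at least 1 added, and the gained windows 3165, 2539 and 2530, so that 10.5%, 10.2% and 9.84% were lost. For Tet2, the lost windows numbered 5250, 3540 and 3540 and the gained 387, 278 and 119, so that 93.1%, 92.7% and 96.7% were lost. Outside the places with shifted input, Tet1 had 117 lost and 2975 gained windows at 0.05, and 67 and 2381 at 0.01. Tet2 there had 4351 lost and 214 gained windows at 0.05, and 2888 and 119 at 0.01. An assumed variation of 10% left 3953 lost windows (26.5%) for Tet1 and 30051 lost and 3976 gained for Tet2. At 20% there were 481 lost and 4649 gained (9.38% lost) and 3805 lost and 539 gained (87.6% lost). With library size alone, 4519 windows (23.2%) and 33715 windows (81.3%) were lost, and scaling to the IP over input ratio of the chromosome 1 run gave 605 lost windows (3.90%) for Tet1 and 1963 gained windows (96.8% lost) for Tet2. These rescalings can remove listed windows but cannot add windows that were not listed. The input offset gave 32.5% lost for Tet1, or 33.1% with the ratio at windows of the same direction, leaving out the shifted places gave 31.8%, or 31.6% without the further segments over the simulated score, and merged regions gave 86.8% lost for Tet2. Thinned Tet2 reads gave 23951 lost and 3553 gained windows (87.1% lost).

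At an adjusted p of 0.01, 24 windows were lost in both knockdowns, and 16.1% of windows listed in both had the same sign, or 93.3% without the chromosome 1 run. The Spearman correlation at this threshold was 0.512 with the run included, and no value without the run is given here. The same-sign share was 89.0% at or above the median signal, 91.2% without the run, 89.6% without the shifted places, 71.8% within 1 window and 90.2% for merged regions. The next shares of Tet1 lost windows leave out the chromosome 1 run, which the counts above include. Chromosome 6 held 29.9% at an adjusted p of 0.01 and 2.74% with the input offset, which brought chromosome 8 to 5.21%. The ratio at windows of the same direction gave 3.02% on chromosome 6 and 7.48% on chromosome 8. Of Tet2 lost windows, chromosome 8 held 18.4% at an adjusted p of 0.01 and 6.66% with the offset, or 6.61% with the ratio at windows of the same direction. Region 83139301 to 83141400 on chromosome 6 changed sign, to a log2 change of 0.13, once its input change was subtracted. The counting interval of that input change does not tell this value from 0.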

Other observations

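The neighbourhood test in this part was chosen after its result was seen. Places that moved in opposite directions in the 2 knockdowns were not limited to identical windows. The shifted places of both knockdowns were left out. Of the 14146 windows gained after Tet1 depletion, 20.8% had a different window lost after Tet2 depletion within 3 kb. The mean was 15.6% (range 14.4% to 17.1%) over 100 placements shifted by up to 200 kb. Windows lost after Tet1 depletion lay there more often, at 50.2% against 22.9% (20.8% to 26.8%). Windows gained after Tet2 depletion did not, at 16.6% against 17.1% (15.8% to 18.4%), and windows gained after Tet1 depletion were beside windows gained after Tet2 depletion in 1.90% of cases against 2.28% (1.89% to 2.69%). That 5hmC gained after Tet1 depletion may arise beside sequence whose 5hmC depends on Tet2 is a hypothesis drawn from this share of 20.8%, which therefore gives it no independent support. Shared fragments between adjoining windows and the parental reads common to both tables were not excluded.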
